A study of Mus musculus with 10 samples.

How the data were processed

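H3K27ac ChIP-seq libraries of the cerebral cortex from 10 mice aged 8 weeks were analysed, 5 heterozygous for a Dnmt3a knockout and 5 wild type. Groups were taken from the genotype labels. The labels name littermates, so replicate numbers mark shared litters: 650 (replicate 1), 119 (replicate 3) and the litter of replicate 5 are male, and 651 (replicate 2) and 141 (replicate 4) female. Deviations from the group means correlated within litters at 0.23, 0.12, 0.080, 0.36 and 0.42 for replicates 1 to 5. After abundance-dependent loess the values were 0.13, 0.14, 0.049, 0.29 and 0.41. The littermate was the best match for replicates 1, 4 and 5 but not for replicates 2 and 3. The description of Het replicate 5 contains the term cKO, while its genotype label says heterozygous; it was used as Het.

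Per the submitters' processing notes, the authors used Bowtie2 and edgeR with the genome build mm9; versions are not given in the sources used here. The deposited values are a signal per region, which the file headers call pseudo-counts: read counts adjusted to a common library size. Per the file headers, the authors' table also gives a log2 fold change, log2 CPM, a p-value and an FDR for each region. The authors' FDR corresponds to 63596 regions tested, and 50898 regions were used here. Region numbers ran to 45320 in the class enh, of which 32614 were present. They ran to 16537 in prom (16529 present) and to 1789 in uaProm (1755 present). The absent numbers thus lie mostly in enh, and results for that class cover the regions present only. How regions were called and classed is not given in the sources used here. Library size adjustment equalises depth between columns. The quantile adjustment also sets each deviation from a group mean to the spread at the common library size. Values of shallow libraries are thereby drawn towards their group mean. The adjustment would hide a uniform change of acetylation.

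Whole reads were recovered by inverting the quantile adjustment at a common dispersion of 0.01508, estimated from the values. The inversion used a separate mean for each genotype, so the deposited values already carry the genotype labels. Splits and swaps of these values can therefore favour the real labels. All values (100%) came out within 0.1 read of a whole number; 9 values deposited as exactly 0 were set to 0 reads. The steps were not linear, so these reads served for depth and for a limma-voom alternative, not for the reported test. Reads in regions were 7101495, 6560497, 5206452, 7066095 and 2771534 for WT replicates 1 to 5 and 5607274, 8453140, 4209117, 5082814 and 6262904 for Het replicates 1 to 5.

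Count tests had been planned; because the values are not counts, limma 3.58.1 (trend, robust) was fitted to log2(value + 1) with sex and genotype as terms and all 10 samples, as the plan foresaw. Fold changes are on that scale, which understates changes of weak regions. The Benjamini-Hochberg threshold was 0.05 and no further filter was applied to the regions present. The interaction was tested as its own coefficient. Region sets were tested with camera (preset correlation 0.01, and estimated) and fry. Shares of signal were compared with exact two-sided permutation tests of 5 against 5 animals (smallest p 0.00794) and sign flips of the 5 litters (smallest p 0.0625). The planned promoter windows needed an annotation, so the authors' region classes took their place, a choice made after seeing the data. The recovery and the limma fits were tested on simulated data with known answers. R 4.3.3, scipy and matplotlib were used.

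Named regions followed a rule fixed before the data were examined: every region past the threshold that moved one way in all litters and, since fewer than 10 passed, the 10 with the smallest p in each direction; for sex, the 5 with the largest fold change per direction on autosomes and on sex chromosomes; for the interaction, the 5 with the smallest p. The chromosome 19 and chromosome 7 regions belong to these. The text gives a part of them in full.

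Alternatives were other scalings, abundance-dependent loess, a filter at a mean of 20, limma-voom, a threshold of 0.10, the litter block, no sex term, the naming style of the labels as a term, and leaving out each library or litter. Pseudocounts of 0.5 and 5, litter as a random effect and the block combined with limma-voom, a pseudocount of 5 or an estimated correlation were added after seeing the data. The gene table at hand was of GRCm38, where genes on chromosome 1 end at 195291439, while regions reach 196959112, so no region was assigned to a gene; the gene lists and cell type markers of the plan, and the Dnmt3a gene itself, were not analysed here.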

Results

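H3K27ac, a histone acetylation mark of active promoters and enhancers, was measured by ChIP-seq in the cerebral cortex of 8-week-old mice that were heterozygous for a Dnmt3a knockout (Het, n = 5) or wild type (WT, n = 5). Dnmt3a is a de novo DNA methyltransferase. The animals formed 5 littermate pairs of 1 Het and 1 WT mouse, 3 of them male and 2 female. The table held pseudo-counts, read counts adjusted to 1 common library size, for 50898 regions in mm9 coordinates, of which 32614 carried the class enh (read here as enhancer), 16529 prom (promoter) and 1755 uaProm, a class that the sources used here do not spell out. Reads in regions, recovered from the pseudo-counts, ranged from 2771534 in WT replicate 5 to 8453140 in Het replicate 2, with no difference between genotypes larger than the spread (exact two-sided permutation p = 0.897). The median was 58 reads per region and library. Regions are named by position, because no gene annotation of mm9 was used here, and H3K27ac at the Dnmt3a gene was not analysed here.

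The first comparison asked where cortical H3K27ac differs between Het and WT littermates. A promoter region at chr3:55583419-55588269 rose in Het, from 82.5 ± 8.12 pseudo-counts in WT to 132 ± 11.6 in Het (SD, n = 5 each), and it was higher in Het in 5 of 5 litters. Its log2 fold change was 0.67 (SE 0.11), or 1.59-fold, with a limma adjusted p of 0.0209 over 50898 regions. No other region passed. In this fit, which leaves the litters out, 1067 regions (2.10%) had an unadjusted p under 0.05. That is fewer than the 1 in 20 that p-values spread evenly would give. With the litter as a block in place of sex, 2357 regions (4.63%) had an unadjusted p under 0.05, so most of that shortfall went with the litters. With this block 3 regions passed, all higher in Het. The block gave the chromosome 3 region an adjusted p of 9.2e-05. It added the uaProm region chr19:6904094-6905922, with 32.8 ± 4.99 pseudo-counts in WT and 59.9 ± 6.43 in Het (log2 fold change 0.86, SE 0.16), whose adjusted p was 0.00245 with the block and 0.123 without it. It also added the promoter region chr7:112910456-112911709, with 21.6 ± 6.30 in WT and 41.3 ± 9.33 in Het (log2 fold change 0.92, SE 0.21), whose adjusted p was 0.0244 with the block and 1.00 without it. Both were higher in Het in 5 of 5 litters. The authors' deposited table lists 2 regions with an FDR under 0.05, the chromosome 3 region (FDR 0.000421) and the chromosome 19 region (FDR 0.00179), both higher in Het. The call of the chromosome 3 region ended when WT replicate 1, 3 or 4 or Het replicate 1, 2 or 4 was left out, with adjusted p from 0.0712 to 0.316, and without the sex term (adjusted p 0.108), while its log2 fold change stayed between 0.62 and 0.71 when single libraries were left out.

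**Figure D1:**
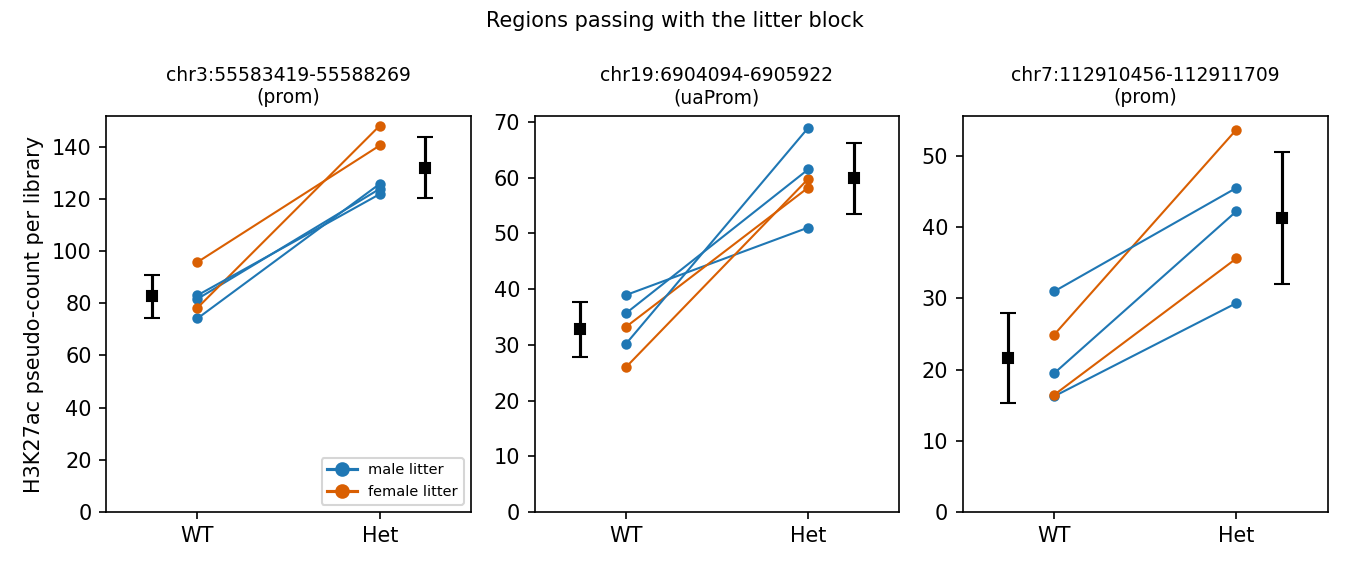
H3K27ac pseudo-counts per library (vertical axis, starting at 0) in WT and Het mice for the 3 regions that passed with the litter block. Lines join the WT and Het animal of a litter, blue for male and orange for female litters, and squares with bars give the group mean ± SD (n = 5); the Het animal lies above its WT littermate in 5 of 5 litters in each region.

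The regions with the next smallest p-values did not pass the test. They were picked as the extremes of 50898 regions, so their differences can overstate any real ones. Their agreement over litters follows in part from the same choice. Among regions with higher values in Het, the uaProm region chr17:17986611-17987932 had 20.8 ± 3.88 pseudo-counts in WT and 37.7 ± 5.02 in Het. The promoter region chr5:93237678-93239076 had 22.7 ± 4.32 and 38.8 ± 6.12, and the enhancer region chr8:130067293-130069177 had 22.2 ± 5.21 and 37.4 ± 6.64. The 10 regions with the smallest p in this direction held 4 promoter, 4 enhancer and 2 uaProm regions, and each was higher in Het in 5 of 5 litters. Among regions with lower values in Het, the enhancer region chr1:121453230-121455804 had 86.1 ± 8.15 in WT and 63.3 ± 4.82 in Het. The enhancer region chr4:131465784-131467341 had 33.9 ± 3.94 and 20.9 ± 6.04, and the promoter region chr5:112741293-112743554 had 64.3 ± 5.52 and 45.9 ± 3.73. The 10 in this direction held 7 enhancer, 2 promoter and 1 uaProm regions; 8 were lower in Het in 5 of 5 litters, and chr10:108216816-108220651 and chr3:55793624-55795688 were higher in 1 litter. The SD of the log2 fold change over all regions was 0.15, and its median standard error was 0.15. The 95% interval of the fold change lay inside 1.5-fold either way in 81.3% of regions. In simulated data with 50 regions changed at each size, the same test recovered 0% of 1.2-fold, 32% of 1.5-fold, 86% of 2-fold and 98% of 3-fold changes. The simulated counts were independent, at a dispersion of 0.02. They held no differences between litters or in signal concentration, so these shares need not hold for the real libraries.

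Enhancer regions had a median log2 fold change of 0.028 and promoter regions of -0.016 between Het and WT. By camera with a preset correlation of 0.01, both classes stood apart from the other regions, each with an adjusted p of 0.0032 over 3 classes, and the 1755 uaProm regions did not (adjusted p = 0.511). With an estimated correlation neither class passed (adjusted p = 0.623 for enhancer and adjusted p = 0.0667 for promoter regions). Fold changes also varied with signal strength, and the median log2 fold change ran from 0.060 in decile 1 of mean signal, the weakest, to -0.019 in decile 10. The medians lay above 0 in 3 of 5 litters in decile 1 and in 2 of 5 in decile 10. Enhancer minus promoter medians were -0.0054, 0.034, -0.0028 and 0.0061 in deciles 1 to 4, above 0 in 2 or 3 of 5 litters, and 0.020 to 0.037 in deciles 5 to 10, above 0 in 4 of 5. Averaged over deciles and litters, the difference was 0.023 (SE 0.025, n = 5), above 0 in 3 of 5 litters (exact sign-flip permutation p = 0.5). Enhancer minus promoter medians averaged 0.045 over litters (SE 0.049, n = 5), above 0 in 3 of 5, with an exact sign-flip permutation p of 0.4375, where the smallest p that 5 litters allow is 0.0625. The share of signal in promoter and uaProm regions was 58.6 ± 1.68% in WT and 58.0 ± 2.28% in Het (SD, n = 5 each; exact two-sided permutation p = 0.627, adjusted p = 0.794 over 5 shares). The strongest 5% of regions held 31.2 ± 1.41% of the signal in WT and 30.9 ± 2.05% in Het (exact two-sided permutation p = 0.770, adjusted p = 0.794). Both differences were smaller than the spread between animals.

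**Figure D2:**
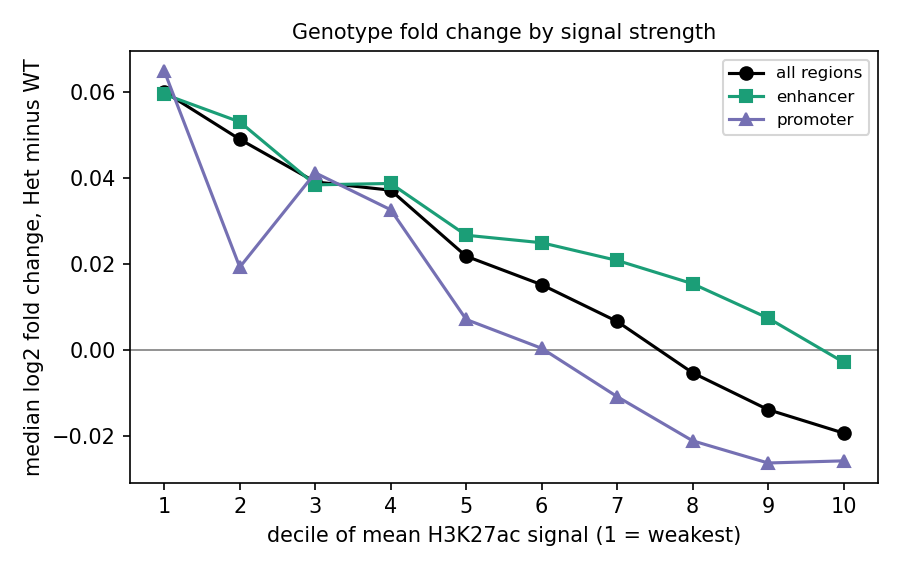
Median log2 fold change of Het minus WT (vertical axis) by decile of mean H3K27ac signal (horizontal axis, 1 = weakest) for all regions, enhancer regions and promoter regions. The line of all regions runs from 0.060 in decile 1 to -0.019 in decile 10.

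Of 33 sets of regions fixed before the data were examined (chromosomes, width, signal strength and clustering), 2 passed by camera with the preset correlation. The 727 regions on chromosome X had a median log2 fold change of -0.027 between Het and WT (adjusted p = 0.0328), and 41.1% of them were higher in Het. Signal quintile 5, the strongest regions, had a median of -0.017 (adjusted p = 0.0239), which abundance-dependent loess moved to -0.0013 (adjusted p = 0.991), while chromosome X still passed with loess (adjusted p = 0.0397). With an estimated correlation neither set passed (adjusted p = 0.995 for each). The median of chromosome X lay above 0 in 2 of 5 litters. By fry no set passed. Fold changes of adjacent regions under 5 kb apart correlated with r = 0.087 across 14953 region pairs, which are not independent replicates. Swapping genotypes within litters gave r from 0.040 to 0.111, and 3 of the 16 swaps, the real labels included, gave a value as high. From 100 to 500 kb apart, r was 0.0047.

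The second comparison, of males with females, checks the labels. It was also planned as a scale for the genotype effect. Sexes, however, differ between litters and genotypes within them, so the 2 counts cannot be set on 1 scale. The 3 promoter regions on chromosome Y carried signal in the 6 males only: chrY:621601-623412 had 48.4 ± 11.6 pseudo-counts in males and 0.117 ± 0.235 in females (SD, n = 6 and 4). On chromosome X, 17 of 727 regions passed, all lower in males; the count was 9 with median-of-ratios factors, 2 to 91 when single libraries were left out, 4 with the litter as a random effect and 0 without both animals of litter 141. The uaProm region chrX:146911975-146913589 had 56.9 ± 13.3 in males and 121 ± 14.5 in females (log2 fold change -1.10, SE 0.15, limma adjusted p 0.000124). The promoter region chrX:17738236-17741880 had 218 ± 43.4 in males and 365 ± 44.5 in females (log2 fold change -0.76, SE 0.12, adjusted p 0.00241). The median over all X regions was -0.19. Both named X regions passed in every setting run but the one without litter 141 (adjusted p over 0.10 for each). The females left in that setting, WT replicate 2 and Het replicate 2, still lay above every male in both regions. In chrX:146911975-146913589 they had 110 and 118 pseudo-counts, against 72.1 in the highest male, WT replicate 3. In chrX:17738236-17741880 they had 323 and 330, against 275 in the same male.

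**Figure D3:**
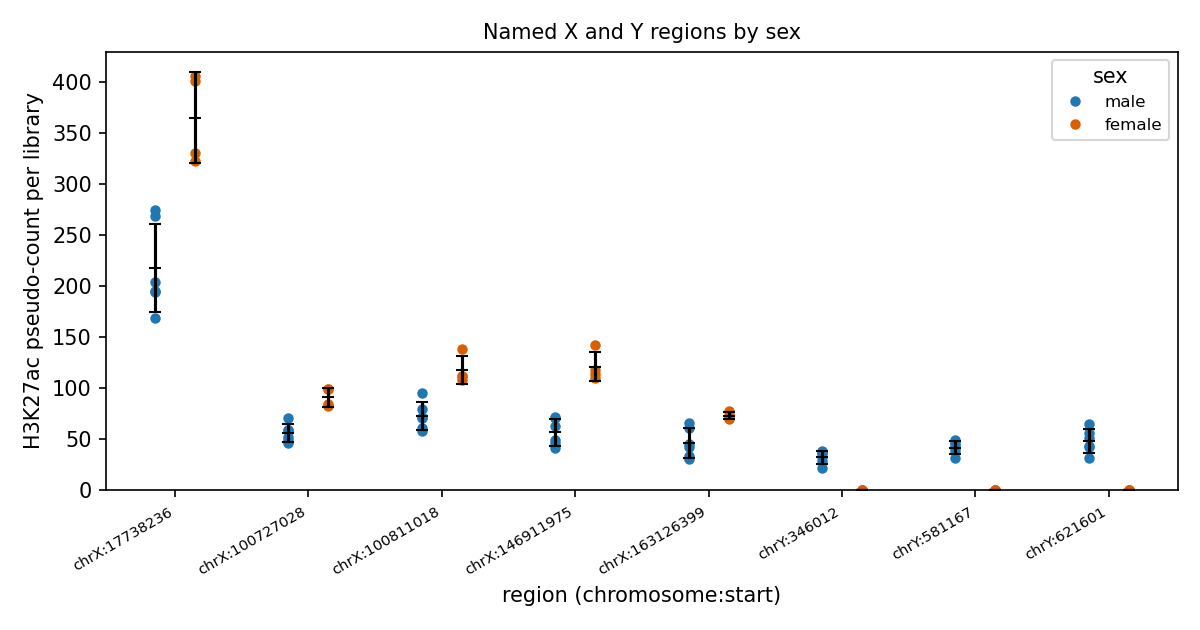
H3K27ac pseudo-counts per library (vertical axis, starting at 0) of the named regions on chromosomes X and Y, for males (blue, n = 6) and females (orange, n = 4), with mean ± SD in black. In the Y regions the females lie at or near 0, and in chrX:146911975-146913589 they average 121 against 56.9 in males.

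On the autosomes, 440 regions passed, 425 higher and 15 lower in males, for 460 in all. The 425 held 225 promoter, 178 enhancer and 22 uaProm regions, with a median log2 fold change of 0.52. The promoter region chr8:42011255-42012350 had 21.4 ± 3.94 in males and 9.99 ± 5.60 in females (log2 fold change 1.22, SE 0.30, limma adjusted p 0.0404), a call lost with median-of-ratios factors (adjusted p 0.0595) and limma-voom (adjusted p 0.0678) and without any 1 of 8 single libraries (adjusted p 0.0682 to 0.371), and the enhancer region chr14:76968498-76970110 had 30.6 ± 6.58 and 14.1 ± 4.15. Among the 15 regions called lower in males, the largest fall was in the promoter region chr6:104442168-104444553. It had 62.2 ± 6.53 in males and 94.3 ± 7.81 in females (log2 fold change -0.60, SE 0.13, limma adjusted p 0.0216). The calls of the last 2 regions ended without WT replicate 4 or 5 or Het replicate 1, 2 or 4, among others. The females came from 2 litters and the males from 3 others, so each sex was also a set of litters. With median-of-ratios factors 94 regions passed, with the litter as a random effect 45, and without both animals of litter 141 only the 3 Y regions did, against 441 regions without both animals of litter 651, the other female litter, of which 201 were among the 460. Leaving out 1 library moved the count by over 1.5 times for WT replicates 2 (978), 3 (90), 4 (14) and 5 (128) and Het replicates 1 (93), 2 (18), 3 (3580), 4 (19) and 5 (95).

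**Figure D4:**
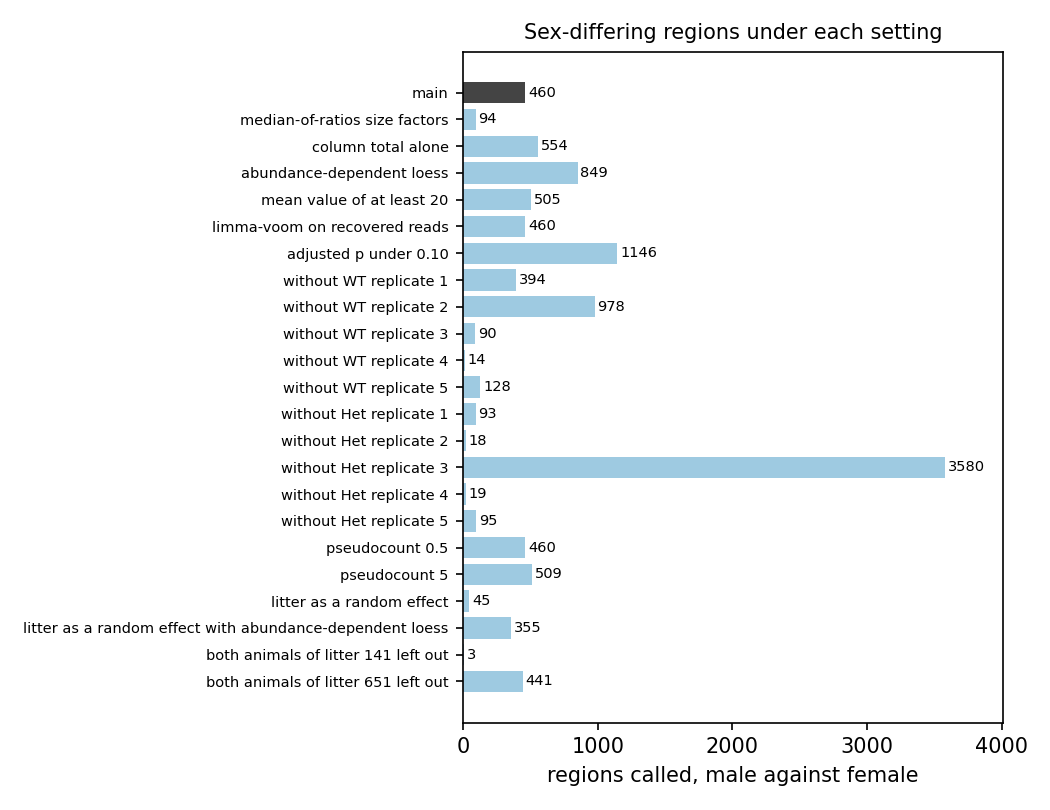
Number of regions called between males and females (horizontal axis, starting at 0) under each setting, with 460 in the reported fit as the dark bar. The bars run from 3 without litter 141 to 3580 without Het replicate 3.

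The third comparison tested whether the genotype effect differs between the sexes. No region passed the limma interaction test. An unadjusted p under 0.05 was found for 694 regions (1.36%), against 1828 (3.59%) with the litter block. Limma-voom on the recovered reads and the litter block also called 0. The region with the smallest p, the enhancer region chr2:167677355-167678187, had a Het minus WT log2 difference of 2.51 (SE 0.56) in females and -0.60 (SE 0.46) in males, with an interaction of -3.11 (limma adjusted p 1.00). Within the 6 males alone no region passed by limma (811 with unadjusted p under 0.05), and within the 4 females none did (957). In females the litter block gave 4 regions, and 57 passed when WT replicate 2 was left out, where 1 WT animal remained and was assumed to vary like the others. The fold changes of males and of females, which share no library, correlated across regions with r = 0.024.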

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

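The splits of the genotype and sex comparisons, the tests of the loess setting, the tests of enhancer against promoter regions and 2 of the 3 divisions of the male litters were chosen after the results were seen; the test of the surrounding segment and the first division of the male litters were written before. Of 93 groups of values tested for a library far from the others, 4 stood out, about the number that chance gives at 1 in 20. WT replicate 4 held 13.9% of its signal in the strongest 1% of regions, against 12.2 to 12.7% in the other WT libraries. Het replicate 1 had 44.3 pseudo-counts at chr3:55793624-55795688, against 22.9 to 29.1 in the other Het libraries. Het replicate 4 had 92.7 at chr12:99772518-99775134, against 99.6 to 100.3 in the other females. The same library had 139 at chrX:100811018-100813498, against 108 to 112 in the other females.

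The chromosome 3 region was the 1 call between genotypes. A change of DNA copy number or of signal over the whole 500 kb on each side was argued against, since the 44 other regions there had a median log2 fold change of -0.024 (SE 0.028). The nearest of them, promoter region chr3:55590375-55595900 at a gap of 2.1 kb, had 0.35 (SE 0.12, limma unadjusted p 0.00701, adjusted p 1.00), so a change over a shorter stretch stays open. The loess setting, run to test differences between libraries in how strongly signal is concentrated in high regions, left the log2 fold change at 0.67 (SE 0.11). Median fold changes by signal decile ran only from 0.060 to -0.019. Loess could therefore hardly have moved this region by 1 SE, and its outcome decides nothing. In decile 8, where the region lies, the median was -0.0054, far smaller than the rise of the region. Of 100 drawn splits of the 10 libraries, 8 gave 1 region or more, the real one included, so chance is not excluded by this count; the highest other gave 1688 and points to a structure of the samples, and the 7 others with a call part 1 or 3 litters, where the real one parts 5. The 16 swaps within litters part 5 litters each. In the same fit they gave 1 region for the real labels and at most 0 for the others. The values were adjusted around a mean for each real genotype, so this count can favour the real labels. With the litter block the real labels gave 3 regions, and 3 of the 16 swaps within litters, the real one included, gave 3 or more. The highest other, with litters 651 and 119 swapped, gave 325, and 16 swaps are too few for a share under 0.05. Under that swap, the share of signal in the strongest 5% of regions differed in the same direction in all 5 litters.

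Between the sexes, 440 autosomal regions passed. Differences in signal concentration that follow mean signal were argued against, since 439 of them still passed with loess. Loess does not correct for the width of regions. The autosomal regions higher in males had a median width of 6636 bp, against 2377 bp for all enhancer and 3057 bp for all promoter regions. A difference between libraries that follows width was not tested. A difference of litter 141 alone stays open, since 3 regions passed without it and 441 without litter 651: in the 440 regions lowest in litter 141 relative to 2 male litters, litter 651 lay below the third male litter by a median log2 difference of -0.31 for replicate 5, -0.23 for replicate 1 and -0.13 for replicate 3, beyond matched random sets of regions in each case, but such sets hold no spread between litters, so the bound set beforehand was wrong for this design, and 1 of 4 litters is the lowest in any case. Of 100 drawn splits into 6 and 4 libraries, 4 gave 460 or more regions, the real one included, a share under 0.05; the highest other gave 9210 and points to a structure of the samples. Sex and litter stay open and cannot be told apart. Of the 10 choices of 2 litters, 3 gave 460 or more, the real one included, and 10 choices are too few for a share under 0.05. The highest other (litter 650 and the litter of replicate 5) gave 3758. In these 2 litters the strongest 5% of regions held 28.2 to 30.5% of the signal, against 30.1 to 33.6% in the others.

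Enhancer regions lay above promoter regions in Het minus WT. With loess the mean difference over litters was 0.022 (SE 0.023), against 0.045 (SE 0.049) without it, so a difference between libraries in signal concentration and a genotype effect cannot be told apart with this spread. The exact sign-flip p over litters was 0.4375, and 5 litters cannot give a p under 0.05. Within males, the real labels gave 0 regions, so each of the 10 splits gives as many whatever its values, and this count tests nothing; the highest other gave 467 and points to a structure of the samples.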

How the results depend on the processing

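The pseudocounts, the litter random effect, the sex comparison without a litter, the class tests, the leave-outs of shares and the settings within each sex were chosen after seeing the data. The genotype comparison gave 1 region under other scalings, loess, the filter, limma-voom, the looser threshold, robust=FALSE, without X and Y, and with either pseudocount. It gave 0 to 1 when single libraries were left out, 0 without the sex term, and 0 without both animals of litter 650, 651 or 141 or of replicate 5 (fewer samples), against 1 without litter 119. The replicate block gave 3 alone, with loess, with limma-voom and with a pseudocount of 5, and the naming style as a term gave 3. The interaction gave 0 under all settings run, the replicate block included.

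The sex comparison gave 94 regions with median-of-ratios factors, 849 with loess, 1146 at the threshold of 0.10, 14 to 3580 without single libraries, 45 with the litter as a random effect (355 with loess) and 3 without litter 141, against 441 without litter 651; limma-voom gave 460. Within females the replicate block gave 4 and single leave-outs 0 to 57; within males all gave 0. Of the planned sets, 0 passed with an estimated correlation, alone, with the replicate block or with loess, and 1 (chromosome X) with loess and the preset correlation, against 2, signal quintile 5 being lost (adjusted p 0.991); of the 3 classes, 0 passed with loess or an estimated correlation. The replicate block changed no other set call. The share of the strongest 5% of regions, -0.33 percentage points in Het, ranged from -0.92 to 0.33 without single libraries, turning above 0 without WT replicate 4 (0.26), Het replicate 1 (0.33) or Het replicate 5 (0.0096), and the promoter share ranged from -1.24 to 0.089, the latter without Het replicate 1. For all these changes the cause was not tested, except where fewer samples are named.

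Over the named regions, no direction reversed in any setting run; 147 values no longer passed (136 of them for 15 regions of the sex comparison) and 10 newly passed (2 regions of the genotype comparison, under the block or the naming style). A count test with DESeq2 was not run. The deposited values are not counts, and the recovered reads were used only for depth and limma-voom. Promoter windows and gene lists were not run, and the setting without a filter removes nothing here. Depth limits weak regions most, with a median of 58 reads per region and library.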

Other observations

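Both hypotheses below were formed on these data; the test of recurrence and the first test of the uaProm class were written before their results were seen, and the second test of that class after the first. If heterozygosity shifted H3K27ac at many regions alike, fold changes of different litters would correlate across regions. The mean of the 10 correlations between litters was -0.00039, ranging from -0.12 to 0.13, and 6 of the 16 swaps of genotype within litters, the real labels included, gave a mean as high, the highest other being 0.079. A genotype effect that recurs over many regions was therefore not seen. Effects at few regions and small effects at many regions remain possible under this test. The log2 fold changes had an SD of 0.15 and a median SE of 0.15, so such small effects would be hard to see.

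The uaProm class makes up 3.45% of regions. In the first test, regions were ranked by their mean difference over litters, on a spread shrunk towards the median spread: 3 of the 100 strongest rises in Het and 3 of the 100 strongest falls were uaProm, and 8 of the 16 swaps within litters, the real labels included, gave as many rises. Ranked by limma with the litter block, a statistic chosen after that count was seen, 6 rises and 7 falls were uaProm, other swaps gave 1 to 7 among the rises, and 2 of the 16 swaps, the real labels included, gave as many. The counts depend on the ranking, and the real labels rank near the top in the second test only. In each test at least 1 other swap gave as many rises, which meets the bound written beforehand for the first test, and the falls held as many uaProm regions as the rises or more.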
